A study of Mus musculus with 24 samples.

How the data were processed

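Mammary epithelial cells were taken from wild-type (WT) and Id4 knockout (KO) female mice of the inbred FVB/N strain, aged 10 to 12 weeks and in estrus. Glands from 4 to 8 mice were pooled for each replicate, per the labels' protocols. Flow sorting of live cells negative for lineage markers, which the sources used here do not list, gave 3 populations: basal cells, luminal progenitors (LP) and mature luminal (ML) cells. The sort used the surface markers CD24, CD29 (integrin beta 1) and CD61 (integrin beta 3). Each of the 6 combinations of genotype and population had 4 biological replicates, which made 24 libraries. Between 0.5 and 2 ng of RNA was amplified into cDNA with the NuGEN Ovation system, per the labels' protocols. The amplified molecules carry no identifiers, so counts include amplification noise, and any limit given from counts covers counting error only.

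The deposited values are expected counts per gene, not normalized, with 1 column per library, as the file header and the values show. The deposited table also gives a gene length, which no test used. The submitters' processing notes name cutadapt, STAR, RSEM and the mm10 build, and their versions, roles and settings are not given in the sources used here. The table held 24007 genes, none at 0 in all libraries, and 25 of them had no symbol. Expected counts were rounded to whole numbers before any test. Gene positions came from the mouse GENCODE annotation on mm10, which held 23780 of the 24007 identifiers (99.1%). An estimated count divides reads between near-identical copies of a gene, so values of such copies are uncertain.

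Library totals ran from 3098433 to 7246445 counts. At these depths 3 counts correspond to between 0.414 and 0.968 CPM (counts scaled to a common library size). The mitochondrial ribosomal RNA genes took 13.5% to 35.1% of a library's counts. No pair of libraries within a group came close to counting noise, with a chi-square per degree of freedom of at least 20.8. Amplification of a single sample can also give that, so the 24 libraries were counted as separate samples from the labels alone. The replicate number was taken from the sample titles. The replicate tags of the KO mature luminal samples repeat a number and differ from the titles, so results that use the numbers in that group rest on the titles.

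Tests used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The test of single genes was edgeR's quasi-likelihood F-test, two-sided, with TMM scaling, the default expression filter, robust dispersion and Benjamini-Hochberg adjustment at 0.05. KO was compared with WT within each population from its own 8 libraries, without a block. The difference of the KO effect between populations was tested in a fit of all 24 libraries, and the WT populations were compared in a fit of the 12 WT libraries. Each of these fits used 1 estimate of a gene's spread for all its populations. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, apart from those said to be added. Levels of single genes are CPM on the scaling of their own fit, while Id4 levels across populations and the plot of 4 genes use a scaling of all 24 libraries. Fitted fold changes of genes at 0 in a group depend on the prior count, so such genes are given by level only.

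The 25 gene lists held 426 symbols, of which 423 matched the table, 4 of them through a synonym. They cover contractile genes, basal identity, stem cell associated genes, luminal progenitor, mature luminal hormone sensing and pan-luminal genes, milk proteins, interstitial matrix, basement membrane, adhesion, E and ID proteins with factors of the epithelial-mesenchymal transition (EMT), TGF-beta and YAP response, Wnt, Notch, cell cycle, interferon, dissociation stress and cholesterol synthesis. The others hold markers of fibroblasts, pericytes, endothelium, immune cells, adipocytes, erythroid cells and Schwann cells. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. A further list, of genes of fatty acid oxidation and related lipid metabolism, was written after the KO comparisons were seen. Genes that include Pdk4, Acot1, Hsdl2 and Slc27a1 had been noticed there, and the list leaves the noticed genes out.

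The rule for named genes took, for KO against WT, the 6 genes with the largest changes in each direction among those that passed, had all libraries separated and reached a mean of 5 CPM in the higher group. Where fewer than 3 genes passed, it took the 3 with the smallest p in each direction, named as not passing, without asking for separation or a minimum CPM. It added Id4 and the 2 members of each list with the smallest p. The WT contrasts took the 5 largest changes in each direction and 2 members of each of 4 identity lists, and the differences between populations took the 4 smallest p in each direction. Genes without a symbol, predicted genes with Gm or Rik names and pseudogenes were left out, and the gate genes Cd24a, Itgb1 and Itgb3 served only to check the sort. The text gives part of these genes by name and the rest as counts. Some genes that the rule took are not reported here. Other genes are named as members of a list, as calls of another tool or after their values were seen.

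Whether equal replicate numbers pair libraries of the 2 genotypes was checked from shared deviations from the group means. All 4 pairs correlated by more than 0.1 in LP (0.138 to 0.402) and in ML (0.135 to 0.344), so the numbers were taken to pair those libraries. Each pool of glands was sorted into the 3 populations, so equal numbers within a genotype were taken as the same pool, which pairs libraries across populations.

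The tests were checked on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. In the basal KO simulation, over 10529 tested genes, 0% of the tested 2-fold and 14.6% of the tested 4-fold genes were recovered. In LP, over 11364 genes, these shares were 13.8% and 58.9%, and in ML, over 11434 genes, 14.1% and 76.5%. False calls made up 1 of 14 calls in basal, 8 of 77 in LP and 4 of 93 in ML, and camera called 0 lists in these 3 simulations. Genes were drawn independently and list members were left unchanged, so these simulations cannot show how camera behaves where genes vary together. For the WT basal against LP contrast, over 12424 genes, 1.02% and 29.9% were recovered, and for the basal against LP difference of KO effects, over 13701 genes, 0% and 14.7%. Both drew from the shared spread of their fit, so they cannot show what a spread that differs between populations does.

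Alternatives covered the scaling, the filter, the tool, a replicate block, all 24 libraries in 1 fit and the removal of each replicate in turn. Others were added after seeing the data. For gene counts these were the removal of ribosomal RNA genes, the removal of the 2 basal libraries least like their group and a term for replicates 1 and 2 against 3 and 4. For lists they were camera on voom values, the filter, scaling and 24-library settings, and, for the WT contrasts and the differences of KO effects, an estimated correlation, the block and the removal of each pool. For correlations of KO effects it was the use of genes with an unadjusted p under 0.05 in either population. The other splits of 8 libraries, or of the 8 pools, into groups of 4 were counted for gene counts and list counts, and for single lists picked after their results were seen.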

Results

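The data are gene counts from 24 libraries of sorted mouse mammary epithelium, 4 for each of 2 genotypes in 3 populations. ID4 is a helix-loop-helix protein that lacks a DNA-binding domain and blocks the E proteins it dimerizes with. The comparison asks what its loss changes in basal, luminal progenitor and mature luminal cells. Library totals ran from 3098433 to 6276496 counts in KO basal cells and from 3180868 to 6524298 in WT basal cells. They ran from 4227099 to 7246445 in WT LP, 3786225 to 6590338 in KO LP, 5474239 to 6958202 in WT ML and 5051805 to 6943383 in KO ML. The first principal component carried 36.2% of the variance and set basal libraries apart from luminal ones, and the second, with 15%, set LP apart from ML. WT basal replicate 2 and KO basal replicate 3 resembled their own group least, with median Spearman correlations of 0.736 and 0.730.

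Replicates 1 and 2 differed from replicates 3 and 4 in both luminal populations, a structure seen after other splits of the libraries had been counted. With genotype in the fit, edgeR called 439 genes in LP between the pairs of replicates (80 higher in replicates 1 and 2, 359 lower), 628 in ML (339 and 289) and 0 in basal cells. At an unadjusted p under 0.05 there were 2441, 2722 and 828, and DESeq2 and voom were not run on this contrast. Camera called 4 lists in LP, 1 in ML and 8 in basal cells, and 0 in each with an estimated correlation. The basal calls included the luminal progenitor and milk lists (camera adjusted p = 0.00346 each), the endothelial list (3.76e-04) and the E protein, ID protein and EMT list (0.0472). Fosl1, a subunit of the AP-1 transcription factor, stood at 46.5 ± 17.0 CPM in LP replicates 1 and 2 and 206.4 ± 51.3 CPM in replicates 3 and 4. Values within each pair of replicates are therefore given beside the leading KO results, each from 2 libraries per genotype.

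Id4 (ENSMUSG00000021379) lies on mm10 chromosome 13 from 48261228 to 48266026 on the plus strand. It was a basal transcript: WT basal libraries held 41.8 ± 31.4 CPM (SD, n = 4, counts of 67 to 595), while all 8 WT luminal libraries held at most 7 counts. KO basal libraries held 5.81 ± 5.54 CPM, 7.19-fold less. KO replicates 1 and 3 kept 10.2 and 10.9 CPM of Id4 (64 and 34 counts), and KO replicates 2 and 4 kept 1.12 and 0.931 CPM. The lowest WT basal value, 13.3 CPM in replicate 2, stood above the highest KO value, and the log2 difference was -3.06 on CPM plus a pseudocount of 0.5. The two-sided exact permutation p was 0.0286, the smallest that 70 assignments allow. Across all genes the edgeR log2 fold change of Id4 was -2.80 (SE 0.87) with an adjusted p of 0.998, which does not pass. Within replicates 1 and 2 it was -3.11, and within replicates 3 and 4 it was -2.42. Which part of Id4 the knockout allele lacks is not given in the sources used here, so the remaining reads were not assigned to an exon.

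**Figure D1:**
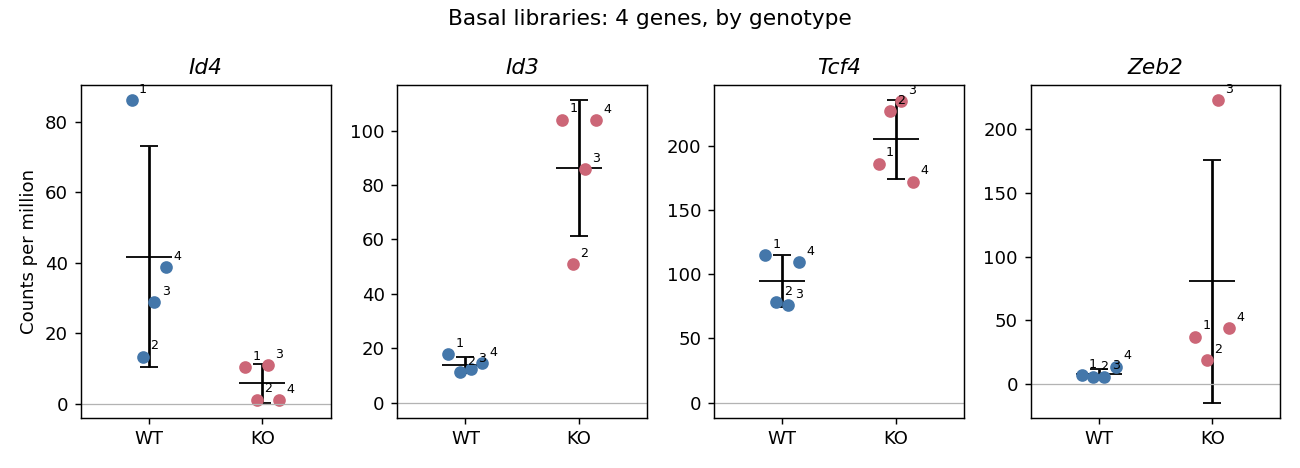
CPM of Id4, Id3, Tcf4 and Zeb2 in the 4 WT and 4 KO basal libraries, scaled over all 24 libraries, with points for libraries (labelled by replicate number) and bars for the mean ± SD. WT and KO libraries do not overlap for any of the 4 genes, and the Zeb2 mean in KO rests largely on replicate 3 at 223 CPM.

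The WT populations were compared first, to see which transcripts set the sorted cells apart. Basal cells were rich in the contractile apparatus of myoepithelium. Acta2, smooth muscle actin, stood at 3676 ± 928 CPM in basal cells and 27.2 ± 5.95 CPM in LP (log2 fold change 7.08, SE 0.40, n = 4, edgeR adjusted p = 3.69e-08). Of 19 tested contractile genes 18 were higher in basal cells than in LP, and 19 when adjusted over the list alone. All 20 tested basal identity genes were higher than in ML, over all genes and adjusted over the list alone. They included Sparc, a matrix glycoprotein (log2 5.53, SE 0.29, edgeR adjusted p = 2.65e-08), and Vim, which encodes the intermediate filament vimentin (log2 4.10, SE 0.34). Of 21 basement membrane genes 18 were higher in basal cells than in LP and 19 higher than in ML, and 1 was lower than in ML.

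Luminal progenitors and mature luminal cells parted on hormone sensing and on milk genes. Of 18 tested hormone-sensing genes 16 were lower in LP than in ML and 1 was higher (17 and 1 adjusted over the list alone). Prlr, the prolactin receptor, stood at 499.7 ± 82.5 CPM in LP and 6200.1 ± 686 CPM in ML (log2 -3.63, SE 0.35, edgeR adjusted p = 1.24e-05). Tbx3, a transcription factor of mammary development, stood at 9.78 ± 4.69 and 157 ± 52.6 CPM. Of 16 luminal progenitor genes 11 were higher in LP than in ML (15 adjusted over the list alone), such as Sox10 (log2 3.6, SE 0.45) and Hey1, a Notch target (log2 5.38, SE 0.75). Of 13 milk genes 8 were higher in LP (10 adjusted over the list alone), and 0 were lower. Against LP, basal cells were lower in 9 of 16 luminal progenitor genes and 8 of 11 pan-luminal genes.

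Genes at 0 in every library of a population were among those with the largest changes. Capn6, a calpain family member, stood at 46.0 ± 26.2 CPM in basal cells and Kcnma1, a potassium channel, at 22.5 ± 7.47 CPM, both at 0 in LP. Cldn2, a tight junction claudin, stood at 15.7 ± 7.85 CPM in LP and at 0 in ML. Slc13a2 was at 8.40 ± 4.39 CPM in LP and at 0 in basal cells. An identifier named Dst (ENSMUSG00000103405) was at 243 ± 149 CPM in basal cells and 0 in LP, and since other identifiers carry the same name its counting is uncertain. Tril stood at 71.1 ± 46.0 CPM in basal cells and 0.121 ± 0.144 CPM in ML, and Ly6d at 87.9 ± 64.3 CPM in ML and 0.193 ± 0.288 CPM in basal cells.

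The genes of the surface markers used in the sort were looked at next. Itgb3 (CD61) was at 183 ± 31.7 CPM in LP and 3.30 ± 1.61 CPM in ML, and Itgb1 (CD29) at 457 ± 147 CPM in basal cells and 241 ± 28.0 CPM in LP (edgeR adjusted p = 0.0150). The Itgb1 call held in 2 of the 5 fits with the replicate block or without a WT replicate, with edgeR adjusted p from 0.00192 to 0.163. Itgb1 was at 295 ± 40.4 CPM in ML, which did not pass against basal cells (edgeR adjusted p = 0.0663, and 0.0136 to 0.357 in the same fits, of which 1 passed). Cd24a was at 699.6 ± 189 CPM in basal cells, 1024 ± 207 CPM in LP and 2202 ± 682 CPM in ML. Among 12771 genes tested with edgeR 2018 differed between basal and LP (1165 higher in basal cells, 853 lower), 3140 between basal and ML (1791 and 1349) and 1470 between LP and ML (845 higher in LP, 625 lower). Without WT replicate 1, 3 or 4 the basal against LP count was 1271, 1214 and 1121, and the LP against ML count 841, 892 and 663. Without replicate 4 the basal against ML count was 1898.

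Camera called 11, 11 and 5 of the 21 tested lists in the basal against LP, basal against ML and LP against ML contrasts, and 5, 6 and 1 with an estimated correlation. The contractile list had an adjusted p of 0.00190 against LP and the hormone-sensing list an adjusted p of 6.02e-04 between LP and ML, both with an estimated correlation. Calls lost with an estimated correlation included the luminal progenitor list (adjusted p = 0.121) and the pan-luminal list (0.0873) between basal and LP, and the milk list (0.310) and the luminal progenitor list (0.125) between LP and ML. The stem cell associated list, called higher in basal cells than in LP (camera adjusted p = 0.0464, and adjusted p = 0.196 with an estimated correlation), had an adjusted p of 0.0679 without replicate 4. Without replicate 3 camera called 9 lists between LP and ML.

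In basal cells no single gene passed between KO and WT, and Id3, another ID protein, had the smallest p. It stood at 88.4 ± 24.1 CPM in KO and 14.0 ± 2.39 CPM in WT basal cells (SD, n = 4), with a log2 fold change of 2.65 (SE 0.42) and an edgeR adjusted p of 0.165. Zeb2, a repressor of epithelial genes, stood at 85.9 ± 106 and 7.69 ± 3.71 CPM, and Tcf4, an E protein, at 212 ± 40.5 and 95.7 ± 16.5 CPM. Id2, also an ID protein, stood at 37.4 ± 10.3 and 13.1 ± 3.11 CPM. All 4 KO libraries lay above all 4 WT libraries for these 4 genes, of which Tcf4 and Id2 were picked after their values were seen.

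Of the 11 tested members of the list of E proteins, ID proteins and EMT factors, 10 had higher fitted values in KO, 0 passed over all genes and 6 passed adjusted over the list alone. The list rose as a group, with a median log2 fold change of 1.5 (camera adjusted p = 1.77e-10), and had adjusted p = 0.0993 with an estimated correlation and adjusted p = 0.0731 with fry. Over its 20 alternatives the adjusted p ran from 4.83e-11 to 0.0993. Zeb1, like Zeb2 a repressor of epithelial genes (log2 2.95, SE 1.06), and Grhl2, an epithelial factor (log2 1.11, SE 0.44), went the same way as Id3, so the members do not share a single function. Tcf3, also an E protein, had a log2 fold change of -0.15 (SE 0.60). The median of the list was 1.32 within replicates 1 and 2 and 1.93 within replicates 3 and 4, and Id3 had log2 fold changes of 2.42 and 2.88 there. In LP Id3 had 1.53 and 0.66 within these pairs and Zeb2 1.84 and 0.69, so higher fitted values of these genes were not particular to basal cells. In ML Id3 had -0.80 and -0.37, and Zeb2 -0.78 and 1.06.

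Among 11307 genes tested with edgeR 0 changed, with 383 at an unadjusted p under 0.05. DESeq2 called 6 genes, all higher in KO and including Id3, Camk1d and Zeb2. Limma's voom with sample weights called 1, Id3 (adjusted p = 0.0450), edgeR without the expression filter called 30, and edgeR on all 24 libraries 13 (4 higher, 9 lower). The last of these fits shares 1 spread with the less variable luminal libraries. Over its 19 alternatives the adjusted p of Id3 ran from 1.01e-06 to 1.00. WT and KO libraries did not overlap for 2.68% of the tested genes, where chance gives 2.86% if the libraries are not paired. Camk1d, a calcium-dependent kinase, had a log2 fold change of 1.97 (SE 0.41). On the lower side stood Igfbp3, which binds insulin-like growth factors (-1.43, SE 0.34), Gpx3, a secreted glutathione peroxidase (-2.01, SE 0.50), and Has2, a hyaluronan synthase (-1.57, SE 0.44), each with an edgeR adjusted p of 0.998.

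Luminal progenitor and milk genes were lower as lists in KO basal cells. The luminal progenitor list fell with a median of -0.81 (camera adjusted p = 5.61e-04), with 14 of 15 members below 0, and had adjusted p = 0.559 with an estimated correlation. Its median was -1.17 within replicates 1 and 2 and -0.72 within replicates 3 and 4. The milk list fell with a median of -1.44 over 11 members (camera adjusted p = 0.00835), and also had adjusted p = 0.559 with an estimated correlation. Without WT replicate 2 the luminal progenitor median was 0.085 (adjusted p = 0.428, with camera's own direction still down) and the milk median 0.34 (adjusted p = 0.478). Over 20 alternatives each, the adjusted p ran from 2.57e-07 to 0.854 for the first list and from 7.25e-08 to 0.633, the latter from fry, for the second. The milk list had an adjusted p of 0.174 without KO replicate 1 and 0.0664 without KO replicate 3. WT replicate 2 held Csn3, a casein, at 3846 CPM and Elf5, a luminal progenitor factor, at 293 CPM. Over 59 abundant LP genes outside the lists its levels would need 27.0% of LP RNA, against at most 6.16% in the other 7 basal libraries.

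Contractile genes had slightly higher values in KO basal cells. Their list rose with a median of 0.29 over 19 members (camera adjusted p = 0.00835), 16 of them above 0, and had adjusted p = 0.559 with an estimated correlation and adjusted p = 0.0530 without WT replicate 2. Its median was 0.06 within replicates 1 and 2 and 0.52 within replicates 3 and 4. Cnn1, calponin, had a log2 fold change of 0.60 (SE 0.27). The Wnt list (median 0.39), the adhesion list (0.25) and the dissociation stress list (0.18) were also called higher, with camera adjusted p of 0.00835, 0.0175 and 0.0115. Each had adjusted p = 0.559 with an estimated correlation. Lgr5, a Wnt pathway receptor, had a log2 fold change of 0.75 (SE 0.32). The Wnt list had an adjusted p of 0.307 without WT replicate 2 and 0.0633 without KO replicate 1. The adhesion list had 0.113 and 0.0962 without WT replicates 2 and 3, and 0.0661 and 0.183 without KO replicates 1 and 3. The stress list had 0.177 without WT replicate 3 and 0.384 without KO replicate 3.

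Endothelial markers moved with these groups. Their list rose with a median of 1.00 over 10 members (camera adjusted p = 0.0115, and adjusted p = 0.559 with an estimated correlation), and without KO replicate 3 it had an adjusted p of 0.221. Cdh5, an endothelial cadherin, stood at 42.6 ± 68.6 CPM in KO and 11.4 ± 9.38 CPM in WT. Of the 22 tested lists 8 were called, 3 without WT replicate 2, 5 without KO replicate 1 and 2 without both WT replicate 2 and KO replicate 3. The lists for basal identity (camera adjusted p = 0.201), stem cell associated genes, mature luminal, pan-luminal, pericyte, Notch and cell cycle genes (each 0.218), basement membrane (0.238), TGF-beta and YAP response (0.535), cholesterol synthesis (0.456), interstitial matrix and interferon (each 0.652), fibroblast (0.596) and Schwann cell genes (0.201) were not called. The medians of the interstitial matrix (-0.03) and cholesterol (-0.04) lists were below 0, while their means, 0.10 for each, and camera's direction were above it. Immune, adipocyte and erythroid markers had 2, 4 and 0 tested members, too few to test.

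**Figure D2:**
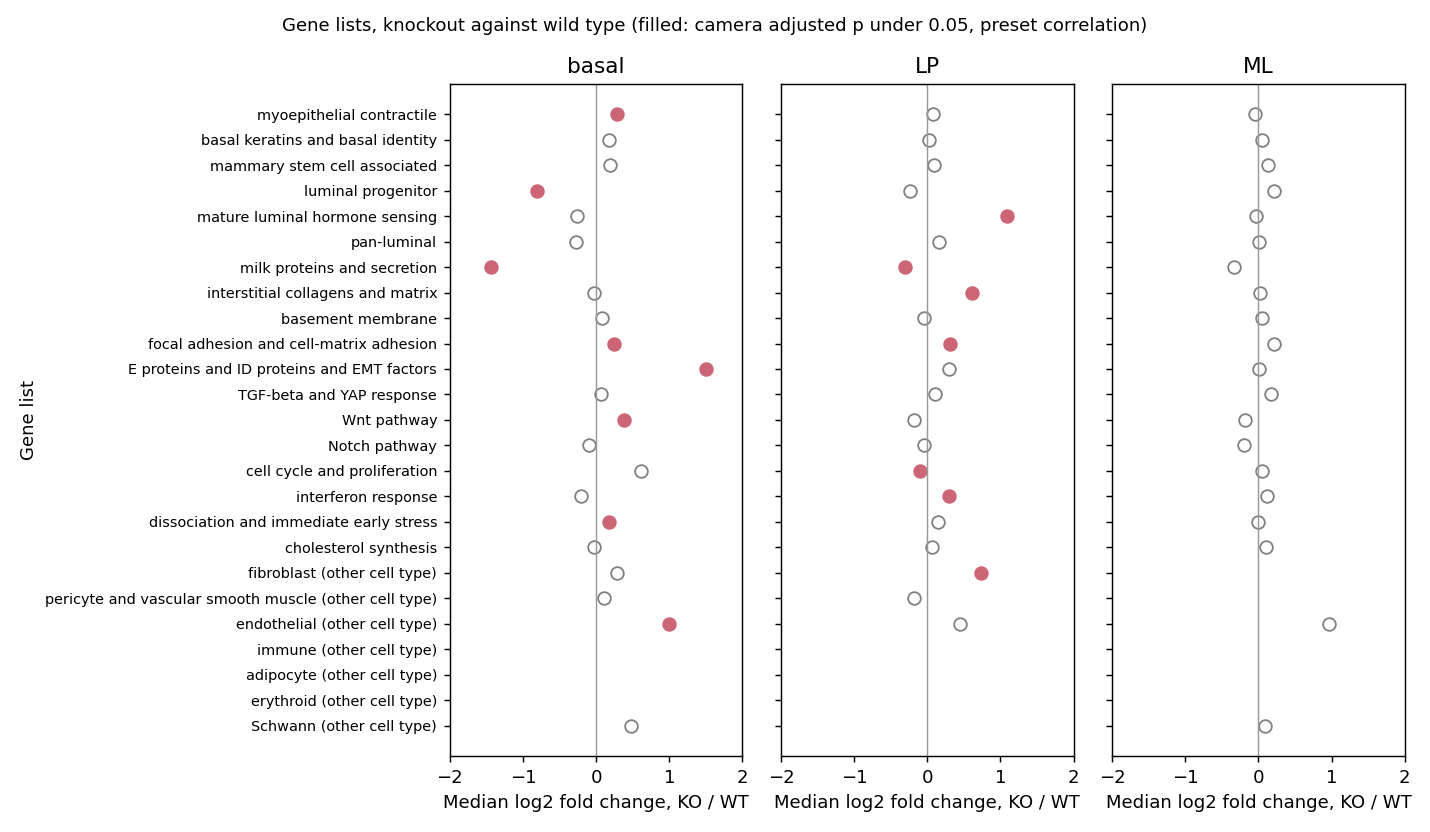
Median log2 fold change, KO over WT, of each gene list with at least 5 tested members in basal, LP and ML cells, where filled points passed camera at an adjusted p of 0.05 with the preset correlation. The median of the E protein, ID protein and EMT list in basal cells is 1.5, and that of the mature luminal list in LP is 1.10.

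In luminal progenitors the KO libraries held more of the transcripts of hormone-sensing mature luminal cells. Esr1, the estrogen receptor, stood at 51.2 ± 9.47 CPM in KO and 26.4 ± 9.33 CPM in WT (SD, n = 4), Prlr at 879 ± 225 and 499 ± 83.2 CPM, and Tbx3 at 29.3 ± 11.3 and 9.78 ± 4.73 CPM. For each of these, as for S100a6 and Ly6a, all KO libraries lay above all WT libraries. The mature luminal list rose with a median log2 fold change of 1.10 over 16 members (camera adjusted p = 2.62e-15), 15 of them above 0, and had adjusted p = 0.123 with an estimated correlation. Over its 19 alternatives the adjusted p ran from 3.34e-22 to 0.149, the latter from fry. Of its members 0 passed over all genes and 6 passed adjusted over the list alone. Gata3, a luminal transcription factor, was the exception in sign (-0.37, SE 0.35).

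Other mature luminal transcripts varied between the LP libraries. Over 52 abundant ML genes outside the lists, the levels in KO LP would need 6.95% ± 7.97 (SD, n = 4) of ML RNA, and those of the list 6.68% ± 6.13, with KO replicate 2 at 18.3% and 15.3%. For the 52 genes KO replicates 1, 3 and 4 were at 5.20%, -0.41% and 4.74%, and WT replicates 1 to 4 at -2.59%, 0.710%, -4.34% and 2.48%, so the mean rests largely on KO replicate 2 and the groups overlap. Without KO replicate 2 the list's median was 0.67 (camera adjusted p = 1.81e-07). The list's median was 1.5 within replicates 1 and 2 and 0.73 within replicates 3 and 4.

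Adhesion genes (median 0.32, camera adjusted p = 2.08e-05), interstitial collagens and matrix (0.60, adjusted p = 2.56e-05), interferon response genes (0.30, adjusted p = 0.00796) and fibroblast markers (0.73, adjusted p = 1.17e-04) rose as lists in KO LP. With an estimated correlation their adjusted p were 0.467, 0.610, 0.664 and 0.664. Another Dst identifier (ENSMUSG00000026131), of a gene that links filaments to adhesion sites, had a log2 fold change of 0.88 (SE 0.25), and Mfap5, a microfibril protein of fibroblasts, of 1.92 (SE 0.70), and neither passed. The fibroblast list had an adjusted p of 0.111 without KO replicate 1. The interferon list had 0.0815 without WT replicate 3, 0.149 without KO replicate 1 and 0.191 without KO replicate 2. The milk list fell (median -0.31, camera adjusted p = 0.0387, and adjusted p = 0.664 with an estimated correlation), as did the cell cycle list (-0.10, adjusted p = 0.00726, and adjusted p = 0.678 with an estimated correlation). The direction of the milk list turned without WT replicate 2 (adjusted p = 0.923), and it had 0.149 and 0.0576 without KO replicates 1 and 3. The direction of the cell cycle list turned without KO replicate 3 (adjusted p = 0.957), and it had 0.286 without WT replicate 2 and 0.0939 without KO replicate 4.

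Among 11700 genes tested in LP with edgeR 0 changed, with 439 at an unadjusted p under 0.05, 8 calls by DESeq2 and 0 by voom. That fit does not use the pairing of replicate numbers. With the replicate block 843 genes had an unadjusted p under 0.05, and 735 with the term for replicates 1 and 2 against 3 and 4. Neither of these fits called a gene. Without KO replicate 2 edgeR called 1 gene, Rspo1, an activator of Wnt signalling, lower in KO. Alcam, an adhesion molecule, stood at 148 ± 29.5 CPM in KO and 76.7 ± 6.31 CPM in WT (log2 0.94, SE 0.21), Marcks, a membrane-bound substrate of protein kinase C, at 50.7 ± 19.7 and 18.9 ± 3.06 CPM, and Man1a, a mannosidase of the Golgi, at 87.1 ± 34.6 and 33.7 ± 9.79 CPM. On the lower side were Slc27a1, a fatty acid transporter (-1.29, SE 0.26), Acot1, an acyl-CoA thioesterase (-1.05, SE 0.26), and Utp14a (-0.93, SE 0.25). Each of these 6 had an edgeR adjusted p of 0.999. Groups did not overlap for 2.82% of genes, against 2.86% if all assignments of libraries to genotypes were equally likely. The pairing of replicate numbers breaks that condition, so the comparison does not show whether the share is at chance.

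The other lists tested in LP were not called. Camera's adjusted p was 0.153 for pan-luminal, 0.203 for contractile, 0.304 for E and ID protein, 0.306 for Notch, 0.444 for pericyte, 0.445 for TGF-beta and for stress, 0.657 for basement membrane, 0.668 for stem cell associated, 0.707 for luminal progenitor, 0.738 for cholesterol, 0.877 for basal identity and for Wnt, and 0.998 for endothelial genes. Median, mean and camera's direction differed in sign for the contractile list (0.07, -0.17, lower), the basal identity list (0.02, -0.08, lower), the basement membrane list (-0.04, 0.04, higher), the Wnt list (-0.18, 0.07, higher) and the endothelial list (0.44, 0.23, lower). Fry called the contractile list alone, as lower in KO (adjusted p = 0.0325). Immune, adipocyte, erythroid and Schwann cell markers had 1, 4, 0 and 2 tested members, too few to test.

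In mature luminal cells the main edgeR fit, which does not use the pairing of replicate numbers, called 1 gene. The fit with the replicate block called 0. Hspa1b, an inducible heat shock protein, stood at 155 ± 21.1 CPM in WT and 56.4 ± 8.84 CPM in KO (SD, n = 4), a log2 fold change of -1.46 (SE 0.19, edgeR adjusted p = 0.0450 in the main fit). Its near-identical neighbour Hspa1a, with which it can share reads, stood at 66.2 ± 7.70 CPM in WT and 32.9 ± 14.0 CPM in KO. The log2 fold change of Hspa1b was -1.33 within replicates 1 and 2 and -1.57 within replicates 3 and 4. The call was lost with the replicate block (adjusted p = 0.106), with DESeq2 size factors (0.0518), with ribosomal RNA genes left out (0.0514) and in each of the 8 edgeR fits that left out a library (0.0808 to 0.431). Over its 18 alternatives the adjusted p ran from 1.88e-08 with DESeq2 to 1.00. The edgeR fit of all 24 libraries called Pappa (adjusted p = 0.0316) in its place.

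Pappa, a protease that cleaves insulin-like growth factor binding proteins, stood at 3.37 ± 2.91 CPM in KO and 41.2 ± 20.9 CPM in WT (log2 -3.56, SE 0.60, edgeR adjusted p = 0.445). On the higher side were Rab6b, a small GTPase (4.09, SE 0.84), Zc3h6 (1.61, SE 0.39) and Ace, angiotensin-converting enzyme (1.18, SE 0.31). Among 11747 tested genes 455 had an unadjusted p under 0.05 in the main fit. With the replicate block there were 821, and 777 with the term for replicates 1 and 2 against 3 and 4. DESeq2 called 8, among them Hspa1b, Pappa, Rab6b and Pdk4, a kinase that restrains pyruvate oxidation, and voom called Hspa1b alone. Groups did not overlap for 2.66% of genes, against 2.86% if all assignments of libraries to genotypes were equally likely. The pairing of replicate numbers breaks that condition here too, so the comparison does not show whether the share is at chance.

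Of 20 lists tested in ML with camera 0 were called, and 5 had an unadjusted p under 0.05: endothelial (0.00471), stress (0.0102), adhesion (0.0147), mature luminal (0.0233) and milk genes (0.0327). Their adjusted p were 0.0942, 0.0979, 0.0979, 0.117 and 0.131. Of the 25 stress genes 1 fell over all genes and 2 adjusted over the list alone, both of them the neighbouring heat shock genes. An estimated correlation called 0 lists and fry 1, adhesion genes (adjusted p = 0.0268). With the replicate block 2 lists were called lower in KO, milk genes (adjusted p = 0.00160) and mature luminal genes (adjusted p = 0.0108), and both had adjusted p = 0.927 with an estimated correlation. Camera called 3 lists without WT replicate 1, 3 without KO replicate 1, 2 without KO replicate 2 and 5 without the expression filter.

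The remaining lists in ML had camera adjusted p of 0.490 for Notch, 0.555 for stem cell associated, cell cycle, interferon and cholesterol, 0.593 for Schwann cell, 0.662 for interstitial matrix, 0.725 for basal identity, luminal progenitor, basement membrane, E and ID protein, TGF-beta and Wnt, 0.940 for contractile and 0.953 for pan-luminal genes. Camera's direction was opposite to the median for the contractile (-0.05, called higher), pan-luminal (0.01), basement membrane (0.05), E and ID protein (0.00) and cell cycle (0.05) lists, and median and mean differed in sign for TGF-beta genes (0.17 and -0.02). Fibroblast, pericyte, immune, adipocyte and erythroid markers had 2, 4, 2, 3 and 1 tested members, too few to test.

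**Figure D3:**
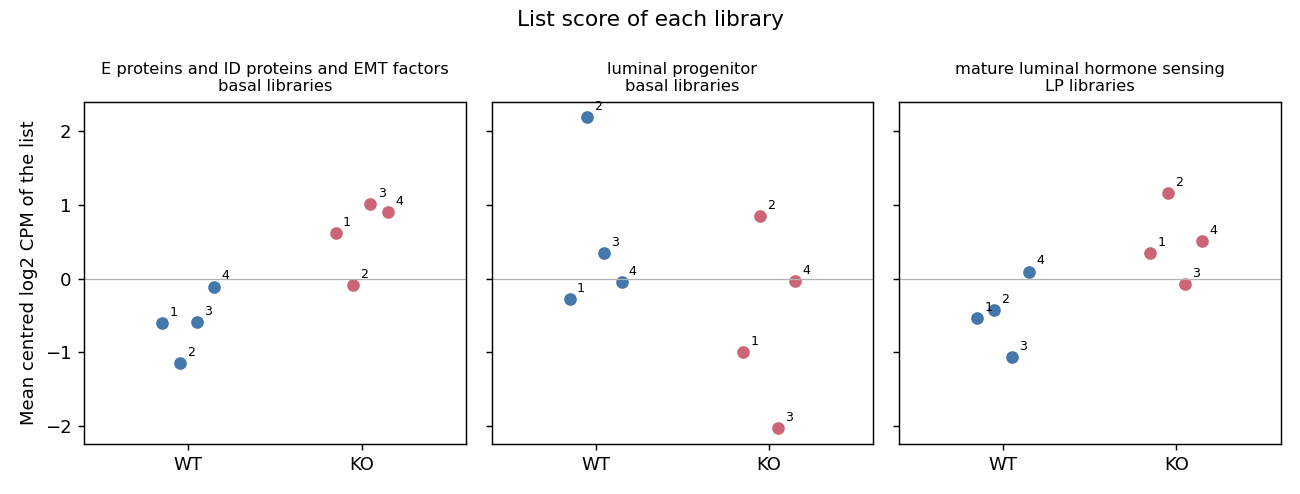
Mean centred log2 CPM of 3 gene lists in each library, for WT and KO, with replicate numbers beside the points. WT basal replicate 2 lies at 2.19 for the luminal progenitor list and KO LP replicate 2 at 1.16 for the mature luminal list, each above the other libraries of its population.

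Whether the KO effect differed between populations was tested directly, and 2 lists stood out, singled out after the results were seen. The list of E proteins, ID proteins and EMT factors had a larger KO effect in basal cells than in LP (median difference 1.58, camera adjusted p = 3.50e-06, and adjusted p = 0.0235 with an estimated correlation). It was also larger in basal cells than in ML (1.35, adjusted p = 9.44e-07, and adjusted p = 0.0114 with an estimated correlation). The mature luminal list had a larger KO effect in LP than in ML (1.29, adjusted p = 3.32e-18, and adjusted p = 0.00119 with an estimated correlation). Its KO effect was smaller in basal cells than in LP (-1.57, adjusted p = 2.27e-08, and adjusted p = 0.0259 with an estimated correlation). In the 8 fits that each left out a pool of mice these 4 calls held, with camera adjusted p of at most 5.56e-04, 2.45e-04, 3.70e-11 and 2.92e-05 in the order given.

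Camera called 7, 3 and 7 of 23 lists for basal against LP, basal against ML and LP against ML, and 2, 1 and 1 with an estimated correlation. The basal against LP count was 4 without KO replicate 3, and the basal against ML count was 7 without WT replicate 1 and 7 without KO replicate 2. The LP against ML count was 3 without WT replicate 2 and 4 without KO replicate 3. Median, mean and camera's direction had a common sign for each called list.

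Of single genes edgeR called 0 of 14082 in each of the 3 differences, with 980, 970 and 186 at an unadjusted p under 0.05, and DESeq2 called 29, 30 and 1. The 24-library fit shares 1 spread between populations that differ in it, so these 3 edgeR counts cannot be compared. For KO against WT, basal cells had 383 of 11307 genes under that p in their own fit and 1787 of 14082 in the 24-library fit. LP had 439 and 321, and ML 455 and 224, in these fits. Id3 had the smallest p for a larger effect in basal cells than in ML (difference 3.27, SE 0.60, edgeR adjusted p = 0.124). Tec, a cytoplasmic tyrosine kinase, had a difference of -5.92 (SE 1.17) between basal cells and LP with an edgeR adjusted p of 0.160, and Esr1 of -2.67 (SE 0.59) with 0.258. Slain1 had a difference of -6.09 (SE 1.19) between basal cells and ML with 0.145. Nbl1, a secreted antagonist of BMP signals, differed by 5.49 (SE 1.41) between LP and ML, and Slit2, a guidance cue, by -3.25 (SE 0.81), both with an edgeR adjusted p of 1.00. Without KO replicate 1 edgeR called 8 genes for basal against LP and 1 for basal against ML. Without WT replicate 2 it called Gm9930 and without KO replicate 4 Esr1 for basal against LP, and without WT replicate 3 Slain1 for basal against ML. The fit without the expression filter called 2 for basal against LP, Gm9930 and Tec.

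Across genes, which are not independent replicates, KO effects correlated with a Pearson coefficient of 0.0785 between basal and LP, 0.0512 between basal and ML and 0.212 between LP and ML. The Spearman values were 0.0869, 0.0460 and 0.211. The populations of a replicate share their mice, so differences between pools enter such correlations.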

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

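The tests of why the mature luminal, E protein and luminal progenitor lists moved, and the splits behind the counts of single genes in the KO comparisons and their differences, were chosen after the results were seen.

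In 2 of 86 groups of 4 libraries the most extreme library stood far from the other 3, where chance gives about 1 in 20 groups. Zeb2 was at 223 CPM in KO basal replicate 3 and between 18.8 and 44.0 CPM in the other KO basal libraries. The mean score of the fibroblast list was 1.10 in WT LP replicate 4 and between -1.06 and -0.90 in the other WT LP libraries.

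The KO effect differed between populations in 17 calls on 11 lists by camera with the preset correlation, and 4 of these calls held with an estimated correlation. All came from a fit that shares 1 spread between populations that differ in it, so calls that involve basal cells may be too strong. Between basal cells and LP the list of E proteins, ID proteins and EMT factors had an adjusted p of 3.50e-06 and the mature luminal list 2.27e-08. Between basal cells and ML the E protein list had 9.44e-07, and between LP and ML the mature luminal list had 3.32e-18. Between basal cells and LP contractile genes also differed (median difference 0.32, adjusted p = 0.00153, and adjusted p = 0.579 with an estimated correlation). The luminal progenitor list (-0.76, adjusted p = 0.00698, and adjusted p = 0.737 with an estimated correlation) lost its call without WT replicate 2 (0.651), KO replicate 1 (0.236) or KO replicate 3 (0.131). The Wnt list (0.87, adjusted p = 0.0245, and adjusted p = 0.667 with an estimated correlation) lost it without WT replicate 2 (0.427) or KO replicates 1 (0.0761), 3 (0.257) or 4 (0.0545). The cell cycle list (0.60, adjusted p = 0.00698, and adjusted p = 0.737 with an estimated correlation) lost it without WT replicate 3 (0.128). The endothelial list (1.10, adjusted p = 0.00466, and adjusted p = 0.579 with an estimated correlation) lost it without WT replicate 1 (0.0738) or KO replicate 3 (0.824).

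Between basal cells and ML the luminal progenitor list differed (median difference -1.34, adjusted p = 0.0107) and lost its call without WT replicate 2 (0.726) or KO replicate 1 (0.114). The dissociation stress list (0.26, adjusted p = 0.0107) lost it without WT replicate 3 (0.0852) or KO replicate 3 (0.413), and both lists had adjusted p = 0.940 with an estimated correlation. Between LP and ML the contractile list (-0.10, adjusted p = 0.0252, and adjusted p = 0.603 with an estimated correlation) lost its call without WT replicate 1 (0.113) or KO replicate 2 (0.549). The interstitial matrix list (0.33, adjusted p = 0.0433, and adjusted p = 0.774 with an estimated correlation) lost it without WT replicates 2 (0.265) or 3 (0.516) or KO replicate 4 (0.0663), and its direction turned without KO replicate 1 (0.785). The adhesion list (0.11, adjusted p = 0.0273, and adjusted p = 0.523 with an estimated correlation) lost it without WT replicates 2 (0.265) or 3 (0.0558) or KO replicate 3 (0.351). The stress list (0.15, adjusted p = 0.0384, and adjusted p = 0.603 with an estimated correlation) lost it without WT replicates 2 (0.141) or 3 (0.612) or KO replicates 3 (0.195) or 4 (0.0612). The pericyte list (-0.92, adjusted p = 0.0252, and adjusted p = 0.213 with an estimated correlation) lost it without WT replicate 4 (0.0713) or KO replicates 2 (0.111) or 3 (0.0907). The endothelial list (-0.85, adjusted p = 0.0252, and adjusted p = 0.603 with an estimated correlation) lost it without WT replicates 2 (0.0880) or 4 (0.0640) or KO replicates 2 (0.111) or 3 (0.954). With the replicate number as a block the interstitial matrix and endothelial lists also lost it (0.0618 and 0.0638).

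The mature luminal list was higher in KO LP. A candidate explanation is mature luminal cells in the KO LP sort. Over 52 abundant mature luminal genes outside the list the implied share was 6.95% ± 7.97, against 6.68% ± 6.13 for the list (SD, n = 4). The LP gate takes CD61-positive cells, which is meant to leave mature luminal cells out, but the purity of the sorted cells was not tested. These means rest largely on KO replicate 2 (18.3% and 15.3%). For the 52 genes KO replicates 1, 3 and 4 were at 5.20%, -0.41% and 4.74% and WT libraries between -4.34% and 2.48%. Without KO replicate 2 the list's median was 0.67 (camera adjusted p = 1.81e-07 with the preset correlation). In mean list score, however, KO replicate 3 (-0.078) lay below WT replicate 4 (0.095). Camera at this setting also called lists in arbitrary splits, so dependence on KO replicate 2 was not excluded. In 2 of 35 splits of the 8 LP libraries the camera p was as small (1.25e-16, against 1.70e-18 in another split), and of the 8 that part all 4 pairs only the real one, but 8 splits are too few for a share under 0.05. A change in LP cells themselves through the loss of Id4 stays open, though WT LP libraries held at most 5 counts of Id4 (0.359 ± 0.345 CPM).

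The list of E proteins, ID proteins and EMT factors was higher in KO basal cells. Endothelial cells (Ptprb at 67.6 ± 39.4 CPM and Cdh5 at 42.6 ± 68.6 CPM in KO) may bring such transcripts where the lineage gate left them. With the endothelial score in the fit the median was 1.23 (1.5 without it), with a camera adjusted p of 2.59e-07. The score is a mean of 10 markers and carries error. The fit therefore cannot remove all endothelial RNA and does not exclude these cells as the source. Without KO replicate 3 the list's median was 1.18, so higher values were not confined to that library. The camera adjusted p there was 2.20e-08 with the preset correlation, a setting at which camera also called lists in arbitrary splits. In 1 of 35 splits, the real one, was the camera p as small (8.06e-12, against 9.74e-08 in the next), but the list was picked after its result was seen, and if equal numbers pair basal libraries too, the 8 splits that part all 4 pairs are too few for a share under 0.05. The fibroblast, pericyte and Schwann cell lists had medians of 0.29, 0.11 and 0.48 in KO basal cells and were not called by camera. Endothelial cells, other stromal cells and a change through the loss of Id4 stay open.

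The luminal progenitor and milk lists were lower in KO basal cells with WT replicate 2 in the fit, and without it the median of the first was 0.085 (SE over members 0.167) in place of -0.81 (SE 0.209). LP transcripts in that library had an implied share of 27.0%. Within replicates 3 and 4, which do not hold that library, the luminal progenitor median was still -0.72, from 2 libraries per genotype. Implied shares there were 5.36% and 0.26% in WT and -2.52% and -0.41% in KO. Whether the fall rests on WT replicate 2 alone was therefore not settled.

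Camera with the preset correlation called many lists in arbitrary splits. In basal cells 7 of 35 splits called at least the real 8 lists (highest other 14). In LP 8 called at least 7 (highest other 11, and 2 of the 8 splits that part all 4 pairs), so chance was not excluded for these 2 counts. In ML the real count was 0, which all 35 splits must reach, so it cannot be judged this way (highest other 9). The contractile list had a camera p of 0.00190 or less in 10 of 35 splits (1.05e-10 in another split), and the luminal progenitor list in basal cells one of 5.10e-05 or less in 11 (1.78e-13 in another). For differences of KO effects over splits of the 8 pools, 9, 16 and 15 of 35 gave at least the real 7, 3 and 7 lists (highest others 10, 11 and 16). Among the 8 splits that part all 4 pairs, too few for a share under 0.05, the highest others were 6, 4 and 5.

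Counts of single genes were 0, 0 and 1 for KO in basal cells, LP and ML, reached in 35, 35 and 4 of 35 splits, with highest others of 2, 392 and 555. A count of 0 is reached by every split, so the shares for basal cells and LP say nothing on chance. The splits with 392 and 555 genes set replicates 1 and 2 of both genotypes against replicates 3 and 4, which points to a structure of the samples. With a term for these pairs the KO counts were 0, 0 and 1. Of the 8 splits that part all 4 pairs, 2 gave at least 1 gene in ML. For the differences of KO effects the real count was 0 genes each, which all 35 splits must reach, so these shares also say nothing on chance (highest others 32, 10 and 1). The WT contrasts had 2018, 3140 and 1470 genes in the real split and at most 1, 0 and 0 in the other 34, so 1 of 35 splits was as large. Equal numbers share a pool there, and the 8 splits that part all 4 pairs are too few for a share under 0.05.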

How the results depend on the processing

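Alternatives added after seeing the data were the removal of ribosomal RNA genes or of the 2 basal libraries least like their group, a term for the pairs of replicates, filters, scalings and the 24-library fit for lists, estimated correlation, block and leave-one-out for WT lists and differences of KO effects, and correlations over genes with an unadjusted p under 0.05. Where a value changed, the cause was not tested.

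For KO in basal cells 0 genes became 30 without the filter, 6 with DESeq2, 1 with voom and 13 with all 24 libraries. The 8 lists became 3 with 24 libraries, 0 with an estimated correlation, 0 with fry and 2 without the 2 basal libraries. Camera adjusted p of the contractile list became 0.121 with 24 libraries, 0.559 with an estimated correlation and 0.261 without the 2 libraries, and that of the luminal progenitor list 0.559 and, with its direction turned, 0.854 in the last 2 of these. The E protein list had 0.0993 with an estimated correlation. Fry, which tests a list against no change and not against other genes, gave adjusted p of 0.583, 0.583 and 0.0731 for these 3 lists. The milk list turned without WT replicate 2 (0.478) and without the 2 libraries (0.0784). In LP DESeq2 called 8 genes, an estimated correlation 0 lists and fry 1, and the mature luminal list had a camera adjusted p of 0.123 with the former and a fry adjusted p of 0.149. The LP milk list turned without WT replicate 2 (0.923) and the cell cycle list without KO replicate 3 (0.957). In ML the 1 gene became 0 with DESeq2 size factors, the replicate block or ribosomal RNA genes left out and 8 with DESeq2, and 0 lists became 5 without the filter, 2 with the block and 1 with fry. For basal against LP, basal against ML and LP against ML differences of KO effects DESeq2 called 29, 30 and 1 genes and an estimated correlation 2, 1 and 1 lists, and without the filter the first had 2 genes. WT lists became 5, 6 and 1 with an estimated correlation. The correlation of KO effects between LP and ML was 0.338 over genes with an unadjusted p under 0.05 in either.

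Leaving out each library or pool in turn gave 0 to 0, 0 to 1 and 0 to 0 genes and 3 to 11, 5 to 9 and 0 to 3 lists for KO in basal cells, LP and ML. Camera adjusted p ran from 1.79e-05 to 0.0530 for contractile, 5.42e-07 to 0.428 for luminal progenitor, 4.83e-11 to 6.59e-08 for E protein and 3.76e-06 to 0.478 for milk genes in basal cells. In LP it ran from 3.34e-22 to 1.81e-07 for mature luminal, 0.00148 to 0.923 for milk and 1.07e-09 to 0.957 for cell cycle genes. Id4 had log2 fold changes of -3.34 to -2.20. Differences of KO effects had 0 to 8, 0 to 1 and 0 to 0 genes and 4 to 10, 2 to 7 and 3 to 8 lists, and the WT contrasts 1121 to 2228, 1898 to 3223 and 663 to 1525 genes and 11 to 14, 11 to 14 and 5 to 9 lists. The leading differences of lists ran from 1.84e-06 to 5.56e-04 and 1.92e-06 to 2.45e-04 for E proteins and from 4.81e-11 to 2.92e-05 and 1.24e-21 to 3.70e-11 for mature luminal genes.

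In basal cells the deviations of equally numbered libraries correlated by 0.0639 to 0.155 (3 of 4 pairs over 0.1), with 8 of 8 libraries best with their own number. With 1 pair under 0.1, and WT and KO pools of different mice, they were not taken as paired, though the same pools gave the luminal libraries that were. The replicate block gave 0 genes, 8 lists and an Id4 log2 fold change of -3.24. With the replicate block LP had 0 genes and 7 lists, differences of KO effects 0 genes each and 9, 3 and 6 lists, and WT 2239, 3294 and 1748 genes and 12, 13 and 6 lists. It ended the calls of Hspa1b and of the interstitial matrix and endothelial lists between LP and ML, added 2 list calls in ML, and ended no other call among the KO results and the lists. Over the alternatives 294 leading values kept their side or stayed within 1.5 times, 61 moved further, 12 lost the call and 1 reversed. Of the values of single genes and other lists 456 kept their side, 65 lost the call, 18 gained one and 4 reversed. The correlation over genes changed in either population was not run, since at most 1 gene changed. Depth limits genes under 0.968 CPM, the level of 3 counts in the smallest library.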

Other observations

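The list of fatty acid oxidation genes was written after genes that include Pdk4, Acot1, Hsdl2 and Slc27a1 had been noticed and leaves the noticed genes out, and the contrast of replicates 1 and 2 with 3 and 4 was also chosen after results were seen.

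Genes of fatty acid oxidation and related lipid metabolism were lower as a group in KO luminal cells. Beside oxidation enzymes the list holds genes such as Angptl4, Plin2, Pex11a and Acot2, which do not encode enzymes of oxidation itself. Angptl4 had log2 fold changes of -0.57 (SE 0.26) in LP and -0.89 (SE 0.30) in ML. The list fell in LP (median log2 fold change -0.34, 15 of 16 members below 0, camera adjusted p = 1.30e-06 over 2 populations, and adjusted p = 0.0251 with an estimated correlation). It also fell in ML (-0.41, 16 of 16 below 0, adjusted p = 1.55e-09, and adjusted p = 0.00116 with an estimated correlation). Hadha, a subunit of the trifunctional enzyme of beta oxidation, had log2 fold changes of -0.84 (SE 0.24) in LP and -0.68 (SE 0.23) in ML, and Acaa2, a thiolase, -1.0 (SE 0.33) in LP. No member passed alone, and 0 passed adjusted over the list alone. The medians within replicates 1 and 2 and within replicates 3 and 4 were -0.45 and -0.22 in LP, and -0.45 and -0.41 in ML.

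A candidate explanation is that the loss of Id4 lowers these genes, and the list fell in LP (1.30e-06) and ML (1.55e-09), but lower genes of the same metabolism had been noticed in these libraries, so this is no independent evidence for it. In 1 of 35 splits each, the real one, was the camera p as small (LP 1.30e-06 against 6.26e-06, ML 7.75e-10 against 3.15e-06), but the replicate numbers pair these libraries, and the 8 splits that part all 4 pairs are too few for a share under 0.05. A difference between the pools of mice went with the data too, since basal cells moved the same way (median -0.51, camera p = 0.0194, and p = 0.145 with an estimated correlation), with medians of -0.46 within replicates 1 and 2 and -0.09 within replicates 3 and 4. The pools are WT or KO, so these explanations cannot be told apart. Without Acot2 and Plin2 the camera p was 8.50e-06 in LP and 6.25e-09 in ML, with Angptl4 and Pex11a still in the list.

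Donor DNA beside the targeted locus was tested as a source of shared changes. Of 31 tested genes within 5 Mb of Id4 13 (41.9%) moved the same way in all 3 populations, against 3162 of 9915 elsewhere (31.9%), with a two-sided Fisher exact p of 0.249. The odds ratio was 1.54 with an interval of 0.694 to 3.33, so 31 genes are too few for the bound set beforehand to exclude the explanation.

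Among genes called by edgeR between replicates 1 and 2 and replicates 3 and 4 in ML, Rpl36 (log2 fold change 1.78) and Rps27 (1.43), which encode ribosomal proteins, were higher in replicates 1 and 2, and Ets2, a transcription factor, was lower (-1.34). Ribosomal protein genes were not tested as a group. In LP Stra6l (-3.63) and Srxn1, an antioxidant enzyme (-2.04), were lower in replicates 1 and 2 and Bmf, a cell death factor, was higher (2.64). Of 422 LP and 611 ML calls among 10903 genes tested in both, 103 were shared, all in the same direction. LP and ML of a replicate were taken to share their mice, so the lists are not independent.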
